A study of Mus musculus with 6 samples.

How the data were processed

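Total RNA was measured in murine induced pluripotent stem (iPS) cells on Illumina bead arrays, in 3 groups of 2 arrays that the labels name after the zebrafish, chick or mouse Nanog protein. Per the labels' protocols, the cells grew in N2B27 medium with LIF, 3 μM CHIR99021 and 1 μM PD0325901. RNA was extracted on RNeasy columns and amplified with a biotin label using the TotalPrep-96 kit. Groups and replicate numbers came from the labels: zebrafish and chick arrays carried the numbers 1 and 2, mouse arrays 4 and 5. Nothing in the labels says whether 2 replicates came from separate lines, clones or cultures, so p-values measure only the spread between these arrays, which may be technical.

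The deposited table holds, per the file headers, a non-normalized mean signal intensity and a detection p-value for each of 45281 probes on each array. Scanner software and background handling were not given in the sources used here. A second deposited table holds the authors' log2 values for 18320 of those probes. Its 6 columns shared one distribution, with a median of 7.44 each, and each column correlated with log2 of its own array's signal at r of at least 0.999, so the scale was log2 of signal after quantile normalization. The filter that chose its probes was not given in the sources used here. Median raw signal ran from 72.6 to 76.1 and 18158 to 18618 probes per array had a detection p-value under 0.05. Mean signal was 351 on mouse replicate 5 and between 297 and 311 on the others. No pair of arrays held identical values.

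Signals were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3. The negative-control distribution was inferred from the detection p-values and the offset was 16. Probes with a detection p-value under 0.05 on at least 2 of the 6 arrays were tested, which left 19899 probes with 13539 gene names. A linear model with 1 coefficient per group was fitted to all 6 arrays, so that the 3 groups shared 1 estimate of spread with 3 residual degrees of freedom, and moderated by eBayes with 6.49 prior degrees of freedom. A change passed at an adjusted p (Benjamini-Hochberg) under 0.05. All log2 changes, standard errors (SE) and adjusted p-values in the text come from this fit unless another is named, with n = 2 arrays per group. A probe without detection on either array of a group has only a bound there. Its fold is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own.

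Names in the deposited table were updated through a RefSeq gene table of the mouse. Of the probes, 27760 carried a current symbol, 7986 matched 1 gene through an older synonym, 23 through the symbol in their definition, and 9512 kept the file's name. No genome was given, so probe positions within transcripts were not analysed here. A gene was represented by its tested probe with the highest mean. The genes named were chosen by a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls per comparison among symbols past the threshold whose groups did not overlap, up to 4 members past the threshold of each fixed gene list (the 2 brightest where none passed), and Nanog, Pou5f1, Sox2, Klf4, Myc, Esrrb, Zfp42, Xist, Ddx3y and Eif2s3y. A symbol meant a name matched in the RefSeq table that does not start with LOC. Nanogpd and BC061212 were named after their values were seen, as were Stra8, Tex19.1, Tdrd1, Slc38a4 (zebrafish minus mouse), Tdpoz1, Tdpoz4, Kit (zebrafish minus chick) and Gja1.

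The 24 lists, fixed before the data were examined, covered pluripotency, embryonic and extraembryonic cell types, fibroblast and neural stem cells, germline and 2-cell-stage-like genes, imprinted and sex chromosome genes, signalling targets, metabolism, stress, interferon, cell cycle, chromatin and reference genes. Each was tested with camera against all other genes at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values for lists were adjusted over the 24 lists of a comparison. Distances between arrays were compared over all 15 pairings of the 6 arrays in an exact permutation test. Because both comparisons with mouse use the same 2 mouse arrays, 1000 sets of unchanged groups were simulated with each probe's spread. Scripts ran in Python 3.11.15 and figures were drawn with matplotlib 3.10.9.

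The fit was tested on simulated data for zebrafish minus mouse over 19899 probes, with 200 changed probes in each of 20 runs. It recovered 100% of simulated log2 changes of 2, 99.0% of rises of 1, 99.4% of falls of 1 and 26.6% of changes of 0.5 with each probe's own spread, and 49.8% of changes of 0.5 with 1 SD for every probe. On average 6.21% of its calls were false with each probe's own spread. A list shifted by 0.5 in simulated arrays over 13539 genes gave an adjusted p of 9.3e-39 with the preset correlation and 0.0651 with the estimated one. The simulated genes varied independently, so the version with an estimated correlation can miss a true shift without any co-regulation. In the real arrays germline genes had a negative estimate (-0.0565) and still did not pass with it. Its adjusted p-values therefore do not tell whether the genes of a list move together. Alternatives covered normalization, offset, probe filter, variance model, fewer arrays, each array left out, a 2-fold threshold, a replicate block, the list test and the rule for several probes per gene. A slide block was not run because no slide is given.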

Results

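Expression was profiled in cells that the labels call mouse iPS cells, a name for somatic cells returned to an embryonic-stem-cell-like state. The labels give E14Tg2A, known as an embryonic stem cell line, as the strain. The 3 groups are named by the origin of Nanog, a homeodomain transcription factor of pluripotent cells: zebrafish, chick or mouse, with 2 arrays each. All cells were kept in LIF with an inhibitor of GSK3 and one of MEK, a medium that holds mouse pluripotent cells in the naive state. The comparisons ask how cells made with a fish or a bird Nanog differ from those made with the mouse protein, and from each other. The small number of arrays limits the precision.

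One Nanog probe, ILMN_1245732, read 11.70 and 11.65 on the mouse arrays and between 7.46 and 7.65 on the 4 others on the log2 scale. It was lower by 17.2-fold in zebrafish Nanog cells (log2 change -4.10, SE 0.13, adjusted p = 4.4e-07) and by 18.1-fold in chick Nanog cells (-4.18, SE 0.13, adjusted p = 3.7e-07). The second Nanog probe, ILMN_2706623, read 11.28 to 11.67 on all 6 arrays and passed in no comparison. Since the 2 probes disagreed, the difference at ILMN_1245732 cannot be read as a fall of the cells' own Nanog transcript. A supplied mouse Nanog transcript, which the group names imply, was not told apart from the cells' own. A probe for the Nanog pseudogene Nanogpd, named after its values were seen, read 10.39 and 10.46 on the mouse arrays and 4.31 to 4.76 elsewhere. It was detected on neither chick array, which puts it at least 52.2-fold lower there, and on 1 of the 2 zebrafish arrays.

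Core pluripotency factors did not pass at any of their tested probes in any comparison. Pou5f1 averaged 12.65 in zebrafish, 12.65 in chick and 12.56 in mouse Nanog cells. Sox2 averaged 9.23, 8.99 and 8.78, Klf4 10.93, 10.77 and 10.73, Esrrb 13.52, 13.66 and 13.55, and Zfp42 11.28, 11.47 and 11.05 in the same order. The largest of these differences was Sox2 in zebrafish minus mouse (0.45, SE 0.13, adjusted p = 0.0875). The zebrafish and mouse arrays did not overlap at either Sox2 probe. Since the fit recovered only 26.6% of simulated changes of 0.5, differences of this size can be missed. Xist, the RNA of the inactive X chromosome, was detected on no array, and Myc was detected on 1 array by 1 of its 2 probes. Y-linked Ddx3y was detected on all 6 arrays.

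**Figure D1:**
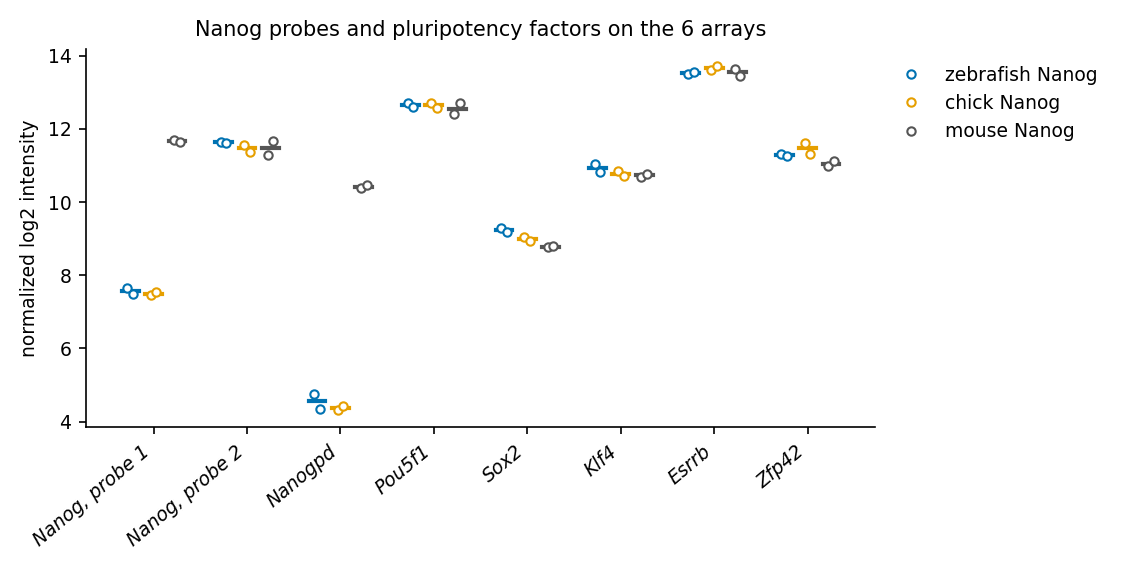
Normalized log2 intensity of the Nanog and Nanogpd probes and of 5 pluripotency factors, with each array as a point and each group's mean as a bar (2 arrays per group). The first Nanog probe (ILMN_1245732) and Nanogpd are bright on the mouse arrays alone, whereas the second Nanog probe (ILMN_2706623) and the 5 factors differ far less among the 3 groups. Sox2 reads 9.295 and 9.173 on the zebrafish arrays and 8.774 and 8.789 on the mouse arrays.

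Zebrafish Nanog cells had less Kit, the receptor of stem cell factor, than mouse Nanog cells, by 5.37-fold (log2 change -2.43, SE 0.13, n = 2 arrays per group, adjusted p = 2.0e-05), and less Aurkc, an Aurora kinase of meiosis, by 6.95-fold (-2.80, SE 0.14). The transmembrane protein genes Ifitm3 and Ifitm1 fell by 2.40 (SE 0.12) and 1.78 (SE 0.13) on the log2 scale, and the transcription factor gene Tfap2c by 1.76 (SE 0.12). In the other direction Lefty2, a secreted inhibitor of Nodal signalling, was 5.68-fold higher (2.50, SE 0.15, adjusted p = 3.8e-05). Fst, which encodes the activin-binding protein follistatin, rose by 1.48 (SE 0.13), and the Wnt-pathway-related gene Dkk3 by 1.73 (SE 0.13).

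In all, 762 of the 19899 probes differed between zebrafish and mouse Nanog cells, 383 higher and 379 lower, and 194 of them by at least 2-fold, 58 higher and 136 lower. The remaining large falls were Calcoco2 (-2.90, SE 0.16), Wfdc2 (-2.30, SE 0.14), the imprinted noncoding RNA Meg3 (-2.06, SE 0.13), Parm1 (-2.01, SE 0.14) and Ncam1 (-1.91, SE 0.13). Slit2 and Slc30a3 were detected on neither zebrafish array and were at least 3.96-fold and 3.01-fold lower. Further large rises were the fatty acid activating enzyme gene Acsl6 (2.04, SE 0.16), Bglap3 (1.89, SE 0.19), Ripply3 (1.71, SE 0.16), Gpr83 (2.84-fold), Cacng5 (1.48, SE 0.12), Igsf21 (1.47, SE 0.12), Ky (1.46, SE 0.12) and the hormone precursor gene Trh (1.44, SE 0.13). A probe that the file names AL022832, a synonym of the X-linked ubiquitin ligase gene Rlim, rose by 2.10 (SE 0.14), but the other tested Rlim probe did not pass, so its gene is uncertain.

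Of 17 measured germline genes, 6 fell and 1 rose, and 11 passed when adjusted over the list alone. Syce1, a component of the meiotic synaptonemal complex, fell by 1.66 (SE 0.17), the DNA methylation cofactor gene Dnmt3l by 1.05 (SE 0.13), and testis tubulin Tuba3a by 1.46 (SE 0.14). Tuba3b (-0.91), Tex19.1 (-0.91, SE 0.14) and Stra8 (-0.87, SE 0.13) fell as well, and Tdrd1 rose by 0.55. Stra8 passed the detection filter only through the mouse arrays and Tdrd1 only through the zebrafish arrays, which favours the direction seen for each. Tuba3a and Tuba3b are near-identical copies that one probe may not tell apart. The list lay below the other genes (adjusted p = 0.00067, and adjusted p = 0.314 with an estimated correlation). The interferon and antigen presentation list was also lower (adjusted p = 0.0096, and adjusted p = 0.314 with an estimated correlation). Its 4 falls among 14 genes were Ifitm1, Ifitm2, Ifitm3 and the histocompatibility gene H2-D1, and none rose, with 6 past when adjusted over the list alone. The median change was -0.12 against a mean of -0.42, and 5 members were higher without passing. The shift thus lay mostly in few genes, the related Ifitm genes among them. Ifitm1 and Ifitm3 are also known as markers of early germ cells. Calls that ended with 1 array left out, each at its highest adjusted p, were H2-D1 (0.0694), Ifitm2 (0.0775) and Tex19.1 (0.0741) without mouse replicate 4, and Tuba3b (0.119) and Tdrd1 (0.178) without mouse replicate 5. Without either zebrafish array Tdrd1 was too dim to be tested, as was Stra8 without either mouse array, and Tdrd1 also missed the threshold in the authors' values, without background correction, with offset 50, with median scaling, with trended variance and in the 4 arrays alone.

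The primitive endoderm list was higher (adjusted p = 0.0146, and adjusted p = 0.314 with an estimated correlation), with 3 rises among 14 genes, Fst, Srgn (0.85, SE 0.19) and Gata6 (0.70, SE 0.14), and 7 past when adjusted over the list alone. Mesendoderm and mesoderm genes were lower (adjusted p = 0.0090, and adjusted p = 0.314 with an estimated correlation) with Gsc (-1.02, SE 0.13) and Cdx1 (-0.67, SE 0.14) past among 10, 3 adjusted over the list alone. The 2-cell-stage-like list was lower (adjusted p = 0.0099, and adjusted p = 0.391 with an estimated correlation) with Tcstv3 (-0.93, SE 0.17) and Gm428 (-0.76, SE 0.13) past among 8, 4 adjusted over the list alone. Cell cycle genes were lower (adjusted p = 0.0090, and adjusted p = 0.314 with an estimated correlation) with the cell cycle inhibitor gene Cdkn2a (-1.08, SE 0.14) and the cyclin gene Ccne2 (-0.64, SE 0.12) past among 24, and the same 2 in number adjusted over the list alone. DNA methylation and chromatin genes were lower (adjusted p = 0.0309, and adjusted p = 0.373 with an estimated correlation) with Tet2 (-1.38, SE 0.13) and Dnmt3l past among 19, 3 adjusted over the list alone. The sex chromosome list was lower (adjusted p = 0.0456, and adjusted p = 0.314 with an estimated correlation) with Y-linked Eif2s3y (-1.51, SE 0.17) alone past among 5, 2 adjusted over the list alone. Without zebrafish replicate 2 the list calls ended for primitive endoderm (adjusted p = 0.0909), mesendoderm (0.0683), DNA methylation (0.201) and sex chromosome genes (0.148), the last also without mouse replicate 5 (0.126) and with median scaling (0.0666). With fry the primitive endoderm and 2-cell-stage-like lists each had an adjusted p of 0.0535. With 1 array left out, the Cdx1 call ended in every fit (log2 change -0.54 without mouse replicate 4). Those of Ccne2 (-0.58) and Srgn (0.56) ended without mouse replicate 4 among others. That of Gata6 (0.61) ended without zebrafish replicate 2 among others, and those of Gm428 (-0.65) and Tcstv3 (-0.89) without mouse replicate 5 among others.

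Among lists that did not shift as a whole, naive pluripotency (adjusted p = 0.0790) held 3 rises, Lefty2, Tbx3 (0.96, SE 0.14) and Gbx2 (0.52, SE 0.12), and 1 fall, Tet2, among 33 genes, 9 past when adjusted over the list alone. Primed epiblast (2 rises of 12) included Otx2, a transcription factor gene of the primed epiblast (1.30, SE 0.17), and trophoblast (1 rise and 2 falls of 11) held Bmp4 (1.20, SE 0.13), Tfap2c and Gata2 (-0.96, SE 0.13). The imprinted list (1 rise and 4 falls of 25) held Igf2 (1.03, SE 0.16), Meg3, Grb10 (-1.06, SE 0.12), Mest (-1.02, SE 0.20) and Slc38a4 (-0.61). The neural stem cell list (1 fall of 6) held Ncam1, and the fibroblast and mesenchymal list (1 rise and 1 fall of 11) held Snai1 (0.75, SE 0.14) and Vim (2-fold lower). Targets of LIF and STAT3 held Gbx2 as a rise and Ly6e (-1.28, SE 0.13), Lifr (-0.66, SE 0.14) and Icam1 (-0.56, SE 0.13) as falls, and WNT targets held Notum (0.88, SE 0.13), Apcdd1 (0.71, SE 0.15) and Cdx1. Phlda1 (0.94, SE 0.14) passed among ERK targets, Ccn2 (-0.75, SE 0.14) and Lefty2 among BMP and TGFβ targets, Egln3 (-1.05, SE 0.16) among glycolysis and hypoxia genes, and Vldlr (-0.66, SE 0.15) among amino acid and ER stress genes. No member passed among p53 targets, cholesterol synthesis, metallothionein and oxidative stress, and reference genes. The calls of Cdx1, Gbx2, Icam1 and Slc38a4 ended whichever array was left out. Adjusted over the list alone, 8 imprinted, 7 glycolysis, 6 trophoblast, 5 primed epiblast, 5 WNT, 5 LIF and STAT3, 3 BMP and TGFβ and 2 fibroblast genes passed, 1 each in the neural, ERK, p53 and amino acid lists and 0 in the cholesterol, oxidative stress and reference lists. The 16 lists that did not shift had an adjusted p between 0.0790 and 0.860. The sign of the median differed from that of the mean and the test for primed epiblast, neural stem cell, ERK, glycolysis and oxidative stress genes. With fry, which tests whether a list's own genes move one way, trophoblast (adjusted p = 0.0029), neural stem cell (0.0475) and LIF and STAT3 genes (0.0475) passed as lower and naive pluripotency genes (0.0117) as higher. Calls ended without a single array, each at its highest adjusted p, for Apcdd1 (0.180) and Mest (0.116) without zebrafish replicate 2, and Ccn2 (0.108), Icam1 (0.189), Lifr (0.188) and Vim (0.0860) without zebrafish replicate 1, and Egln3 (0.0741), Igf2 (0.0893), Phlda1 (0.0680), Snai1 (0.158), Tbx3 (0.0671) and Vldlr (0.228) without mouse replicate 4, and Gbx2 (0.195) and Slc38a4 (0.210) without mouse replicate 5.

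The count fell to 325 without zebrafish replicate 1, 406 without zebrafish replicate 2, 254 without mouse replicate 4 and 328 without mouse replicate 5, and median scaling gave 235 higher and 553 lower. Of the 62 named calls, 39 passed whichever array was left out and 48 in all other settings, with Lifr lost in the authors' values, Apcdd1, Gbx2, Snai1 and Srgn with median scaling, and Cdx1, Lifr, Mest and Vldlr as a mean over the gene's tested probes among the others.

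Chick Nanog cells had more of a set of transcripts known from the 2-cell embryo than mouse Nanog cells. Zscan4c, a zinc finger gene of that stage and of a small fraction of stem cells, was 2.77-fold higher (log2 change 1.47, SE 0.16, n = 2 arrays per group, adjusted p = 0.0023). Gm428 was 3.37-fold higher (1.75, SE 0.13, adjusted p = 0.00038), and Tcstv1 and Tcstv3 rose by 1.16 (SE 0.14) and 1.07 (SE 0.17). Tdpoz4 (1.02, SE 0.18) and Tdpoz1 (0.83, SE 0.16) were higher too. Of the 18 members of the list 8 were measured, of which 6 rose and none fell, with 7 past when adjusted over the list alone. The list lay above the other genes (adjusted p = 2.0e-09, and adjusted p = 0.229 with an estimated correlation). Leaving out either chick array left 6 measured members. The others, Tdpoz4 among them, passed the detection filter only with the help of a chick array, which favours a rise there. Zscan4, Tcstv and Tdpoz genes have near-identical copies that one probe may not tell apart. Calls that ended with 1 array left out, each at its highest adjusted p, were Tcstv1 (0.0552), Tcstv3 (0.129), Tdpoz4 (0.182) and Tdpoz1 (0.202) without mouse replicate 4. Without either chick array Tdpoz4 was too dim to be tested.

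In all, 402 probes differed between chick and mouse Nanog cells, 213 higher and 189 lower, and 130 of them by at least 2-fold, 65 each way. Other large rises were Lefty2 (1.59, SE 0.15), AF067061 (1.56, SE 0.16), Gm9124 (1.54, SE 0.14), Pramel39 (1.53, SE 0.17), Mup6 (1.52, SE 0.13), Tmem92 (1.29, SE 0.15) and the AL022832 probe (4-fold). The arginase gene Arg2 was detected on neither mouse array and was at least 2.37-fold higher. Probes that the file names C130035G06RIK and 4933421H10RIK, matched as synonyms to Tnfrsf22 and Cgnl1, rose by 1.37 (SE 0.13) and 1.31 (SE 0.22), but no other probe of either gene passed. Apart from the Nanog and Nanogpd probes, large falls were Meg3 (-2.06, SE 0.13), Trim50 (-2.03, SE 0.15), Wfdc2 (-1.95, SE 0.14), Calcoco2 (-1.89, SE 0.16) and Gpnmb (-1.83, SE 0.14). Ifitm3 (-1.81, SE 0.12), the actin-bundling gene Lcp1 (-1.62, SE 0.18), the Fc receptor gene Fcgr2b (-1.60, SE 0.18), S100a1 (-1.57, SE 0.13), Kit (-1.55, SE 0.13), the zinc transporter gene Slc30a2 (-1.53, SE 0.14) and Ncam1 (-1.49, SE 0.13) fell as well. Dependent on single arrays, each at its highest adjusted p with 1 left out, were Arg2 (0.0619) without mouse replicate 4, and Cgnl1 (0.146) without chick replicate 2.

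Trophoblast genes were lower in chick than in mouse Nanog cells (adjusted p = 0.0027, and adjusted p = 0.229 with an estimated correlation). Tfap2c fell by 1.32 (SE 0.12), the keratin gene Krt8 by 0.79 (SE 0.16) and Tead4 by 0.69 (SE 0.13), and none of 11 rose, with 6 past when adjusted over the list alone. Germline genes were lower (adjusted p = 0.0066, and adjusted p = 0.229 with an estimated correlation) with Syce1 (-1.16, SE 0.17) and the cohesin gene Smc1b past among 17, 5 adjusted over the list alone. Smc1b was detected on neither chick array and was at least 1.37-fold lower, a call that ended without background correction, in the authors' values, with offset 50 and with no filter. The interferon list was lower (adjusted p = 0.0270, and adjusted p = 0.414 with an estimated correlation) with Ifitm3, Ifitm1 (-1.47, SE 0.13) and Ifitm2 (-0.77, SE 0.13) past among 14, 4 adjusted over the list alone, although its median change was 0.01. Without mouse replicate 4 the interferon call ended (adjusted p = 0.131). Calls ended without a single array, each at its highest adjusted p, for Ifitm2 (0.129) and Syce1 (0.107) without mouse replicate 4, and Krt8 (0.230) without mouse replicate 5, and Smc1b (0.233) and Tead4 (0.216) without chick replicate 2.

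Naive pluripotency genes were higher (adjusted p = 0.0120, and adjusted p = 0.229 with an estimated correlation), with 3 rises among 33, Lefty2, Gbx2 (0.85, SE 0.12) and Zfp296 (0.59, SE 0.13), and 8 past when adjusted over the list alone. The Zfp296 call ended whichever array was left out. Primitive endoderm genes were higher (adjusted p = 0.0276, and adjusted p = 0.411 with an estimated correlation), with rises of the collagen gene Col4a1 (0.97, SE 0.15) and Fst (0.70, SE 0.13) and a fall of Dab2 (-1.17, SE 0.14) among 14, 5 past when adjusted over the list alone. ERK targets were higher (adjusted p = 0.0331, and adjusted p = 0.339 with an estimated correlation), with Etv1 (0.74, SE 0.14) past among 14 and 3 past when adjusted over the list alone. Without mouse replicate 4 all 3 list calls ended (adjusted p = 0.121 for naive pluripotency, 0.0679 for primitive endoderm and 0.182 for ERK targets), as did primitive endoderm without chick replicate 2 (0.152) and ERK targets without chick replicate 1 (0.119). With median scaling naive pluripotency and ERK targets both had an adjusted p of 0.0505, and with fry primitive endoderm had one of 0.123. Calls that ended with 1 array left out, each at its highest adjusted p, were Col4a1 (0.0962) without chick replicate 1, and Etv1 (0.207) and Zfp296 (0.252) without mouse replicate 4, and Fst (0.216) and Gbx2 (0.0765) without chick replicate 2.

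The other 17 lists had an adjusted p between 0.0703 and 0.978. Among them the WNT targets Notum (0.95, SE 0.13), Apcdd1 (0.84, SE 0.15) and Fzd7 (0.68, SE 0.12) rose, as did Snai1 (0.94, SE 0.14) of the fibroblast list. Ncam1 of the neural stem cell list, Meg3 and Slc38a4 (-0.83, SE 0.14) of the imprinted list and Plk2 (-0.69, SE 0.12) of the p53 targets fell. Ccnd2 of the cell cycle list and the cystine transporter gene Slc7a11 of the amino acid and oxidative stress lists were detected on neither mouse array and were at least 1.67-fold and 1.62-fold higher. Slc7a11 passed the detection filter only through the chick arrays, which favours a rise there. Gbx2 passed among LIF and STAT3 targets and Lefty2 among BMP and TGFβ targets. No member passed among primed epiblast, mesendoderm and mesoderm, sex chromosome, glycolysis and hypoxia, cholesterol synthesis, DNA methylation and chromatin, and reference genes. Adjusted over the list alone, 6 WNT, 5 fibroblast, 4 mesendoderm, 4 imprinted, 4 LIF and STAT3, 3 BMP and TGFβ and 2 cell cycle genes passed, 1 each in the neural, p53, amino acid and oxidative stress lists and 0 in the others. With fry, neural stem cell (adjusted p = 0.0336) and oxidative stress genes (0.0336) passed as lower and WNT targets (0.0404) as higher. The median of the imprinted and reference lists differed in sign from their mean and test. Dependent on single arrays, each at its highest adjusted p with 1 left out, were Apcdd1 (0.198), Ccnd2 (0.205), Fzd7 (0.149) and Plk2 (0.150) without chick replicate 2, and Notum (0.0643) and Slc38a4 (0.149) without chick replicate 1, and Slc7a11 (0.0769) and Snai1 (0.122) without mouse replicate 4. Without either chick array Slc7a11 was too dim to be tested.

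The count fell to 141 without chick replicate 1, 94 without chick replicate 2, 86 without mouse replicate 4 and 120 without mouse replicate 5. Median scaling shifted the median of all probes by -0.12 and gave 143 higher and 376 lower, and of the 49 named calls 27 passed whichever array was left out and 35 in all other settings, with Etv1, Fst, Fzd7 and Zfp296 lost with median scaling, and Cgnl1, Etv1, Slc7a11, Tead4, Tnfrsf22 and Zfp296 as a mean over the gene's tested probes among the others.

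**Figure D2:**
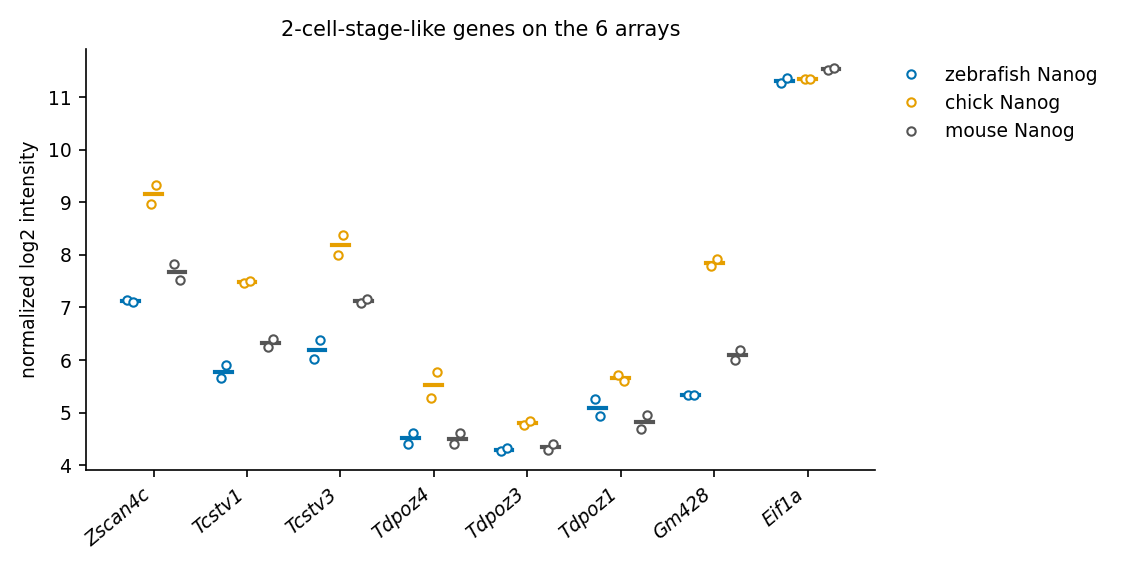
Normalized log2 intensity of the 8 measured 2-cell-stage-like genes, with each array as a point and each group's mean as a bar (2 arrays per group). Gm428 averages 7.85 in chick, 6.10 in mouse and 5.34 in zebrafish Nanog cells, and Eif1a lies close together in all 3 groups.

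The direct comparison of zebrafish with chick Nanog cells had large differences at 2-cell-stage-like genes and at Acsl6. Gm428 was 5.72-fold lower in zebrafish Nanog cells (log2 change -2.51, SE 0.13, n = 2 arrays per group, adjusted p = 0.00010), Zscan4c 4.08-fold lower (-2.03, SE 0.16, adjusted p = 0.00045) and Tcstv3 3.99-fold lower. Of the 8 measured members 5 fell, Gm428, Zscan4c, Tcstv3, Tcstv1 (-1.71, SE 0.14) and Tdpoz4 (-1.02, SE 0.18), whereas Tdpoz1 did not pass, none rose, and 7 passed when adjusted over the list alone. The detection filter favours a fall for members that passed it only with a chick array. The list lay below the other genes (adjusted p = 2.4e-12, and adjusted p = 0.253 with an estimated correlation). Acsl6 was 7.75-fold higher in zebrafish Nanog cells (2.95, SE 0.16, adjusted p = 0.00010), and the epiblast transcription factor gene Otx2 2.59-fold higher (1.37, SE 0.17, adjusted p = 0.0045). Calls ended without a single array, each at its highest adjusted p, for Otx2 (0.0678) without chick replicate 2, and Tdpoz4 (0.140) without zebrafish replicate 1. Without either chick array Tdpoz4 was too dim to be tested.

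In all, 398 probes differed, 168 higher and 230 lower in zebrafish than in chick Nanog cells, and 105 by at least 2-fold, 24 higher and 81 lower. Further large rises were Ripply3 (1.79, SE 0.16), Cox6a2 (1.47, SE 0.17), Cacng5 (1.44, SE 0.12), Bglap3 (1.33, SE 0.19), the matrix protein gene Matn1 (1.30, SE 0.12), Unc45b (1.20, SE 0.12), Arhgap8 (1.18, SE 0.18), the endocytic adaptor gene Dab2 (1.15, SE 0.14) and the calretinin gene Calb2 (1.14, SE 0.13). Id3, a target of BMP signalling, rose by 1.29 (SE 0.16). Further large falls were the surface peptidase gene Dpp4 (-2.18, SE 0.17), AF067061 (-2.01, SE 0.16), BB287469 (-1.75, SE 0.17), Pacsin1 (-1.66, SE 0.16), Aurkc (-1.65, SE 0.14), Gm9124 (-1.65, SE 0.14) and the C130035G06RIK probe of Tnfrsf22 (-1.62, SE 0.13). Pramel39 was detected on neither zebrafish array and was at least 3.44-fold lower. Calls that ended with 1 array left out, each at its highest adjusted p, were Arhgap8 (0.0876) without zebrafish replicate 2, and Bglap3 (0.0995) and Id3 (0.0616) without chick replicate 2, and Dab2 (0.0535) without chick replicate 1.

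Cell cycle genes were lower in zebrafish than in chick Nanog cells (adjusted p = 0.00029, and adjusted p = 0.253 with an estimated correlation). Among 24 measured genes the cell cycle inhibitor gene Cdkn2a (-0.73, SE 0.14) alone passed, 4 were higher, and 6 passed when adjusted over the list alone. DNA methylation and chromatin genes were lower (adjusted p = 0.0155, and adjusted p = 0.391 with an estimated correlation) with Tet2 (-0.90, SE 0.13) and Dnmt3l (-0.74, SE 0.13) past among 19, 3 adjusted over the list alone. The sex chromosome list was lower (adjusted p = 0.0062, and adjusted p = 0.354 with an estimated correlation) with Eif2s3y (2-fold lower) and Zfy1 (-0.74, SE 0.13) past among 5, 3 adjusted over the list alone, and Y-linked Ddx3y at -0.39 (SE 0.12, adjusted p = 0.169). The p53 target list was higher (adjusted p = 0.0061, and adjusted p = 0.391 with an estimated correlation) with no member past among 16 and 1 past when adjusted over the list alone. The p53 target call ended without zebrafish replicate 1 (adjusted p = 0.0746) and the DNA methylation call without zebrafish replicate 2 (adjusted p = 0.185). With 1 array left out, the Cdkn2a call ended in every fit (log2 change -0.61 without chick replicate 1). It also ended when the 4 arrays compared were fitted alone. Those of Dnmt3l (-0.70) and Zfy1 (-0.68) ended without chick replicate 1 among others. Those of Eif2s3y (-0.78) and Tet2 (-0.80) ended without chick replicate 2 among others.

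The other 19 lists had an adjusted p between 0.0894 and 0.895. Otx2 of primed epiblast, Lefty2 (0.91, SE 0.15) of the naive pluripotency list, Lefty2 and Id3 of the BMP and TGFβ list, Dab2 and Fst (0.78, SE 0.13) of primitive endoderm, Bmp4 (0.63, SE 0.13) of trophoblast, Ddit4 (0.73, SE 0.14) of glycolysis and hypoxia and Gstm2 (0.64, SE 0.13) of oxidative stress rose. Tet2 of the naive pluripotency list, Tuba3a (-1.14, SE 0.14) and Dnmt3l of the germline list, Gsc (-0.63, SE 0.13) of mesendoderm, Cdx1 (-0.88, SE 0.14) of mesendoderm and of WNT targets, Gata2 (-0.68, SE 0.13) of trophoblast, Grb10 (-0.92, SE 0.12) of the imprinted list and Etv4 (-0.95, SE 0.14) of ERK targets fell. H2-D1 (-0.84, SE 0.12) and Ifitm3 (-0.59, SE 0.12) of the interferon list and Lifr (-0.77, SE 0.14) and Ly6e (-0.69, SE 0.13) of LIF and STAT3 targets fell too. Slc7a11 was detected on neither zebrafish array and was at least 1.63-fold lower, a direction favoured by a detection filter that it passed only through the chick arrays. No member passed among neural stem cell, fibroblast and mesenchymal, cholesterol synthesis and reference genes. The calls of Bmp4, Gata2, Gsc, Gstm2, Ifitm3 and Ly6e ended whichever array was left out. Adjusted over the list alone, 9 germline, 6 trophoblast, 4 primed epiblast, 4 oxidative stress, 3 primitive endoderm, 3 imprinted, 3 BMP and TGFβ and 3 interferon genes passed, 2 each in the naive pluripotency, mesendoderm, WNT, LIF and STAT3 and glycolysis lists, 1 each in the ERK and amino acid lists and 0 in the others. With fry, germline (adjusted p = 0.0408) and ERK targets (0.0408) passed as lower and trophoblast (0.0194), BMP and TGFβ (0.0411) and oxidative stress genes (0.0408) as higher. Median signs differed from those of the mean and the test for neural stem cell, primitive endoderm, WNT, LIF and STAT3, and cholesterol genes. Calls ended without a single array, each at its highest adjusted p, for Bmp4 (0.251), Cdx1 (0.124), Ddit4 (0.237), Etv4 (0.0856), Gata2 (0.175), Grb10 (0.0650), Gsc (0.244), H2-D1 (0.102), Ifitm3 (0.258), Lefty2 (0.131), Ly6e (0.221) and Tuba3a (0.0589) without chick replicate 2, and Fst (0.141) and Gstm2 (0.205) without chick replicate 1, and Lifr (0.176) and Slc7a11 (0.120) without zebrafish replicate 1, and without either chick array Slc7a11 was too dim to be tested.

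The count fell to 108 without zebrafish replicate 1, 140 without zebrafish replicate 2, 97 without chick replicate 1, 61 without chick replicate 2 and 253 without mouse replicate 4. Only 264 probes passed when the 4 arrays compared were fitted alone, and of the 45 named calls 19 passed whichever array was left out and 28 in all other settings, with Zfy1 lost in the authors' values and without background correction, Bmp4, Gata2, Gsc, Ifitm3 and Ly6e with median scaling, and Arhgap8, Cdkn2a, Grb10, Lifr and Slc7a11 as a mean over the gene's tested probes among the others.

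**Figure D3:**
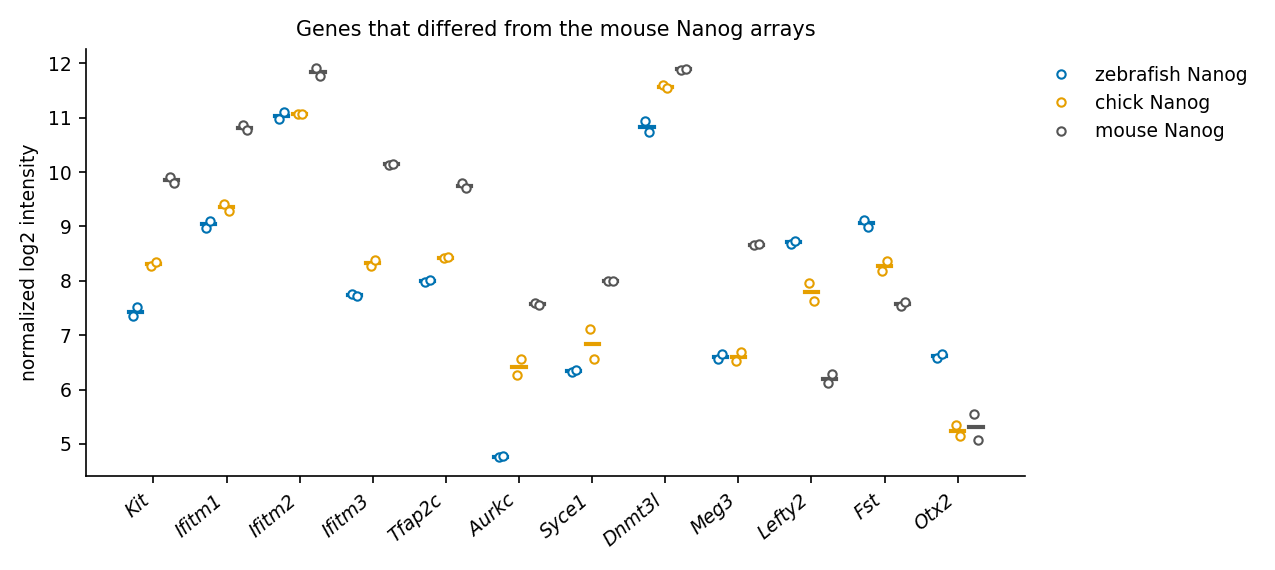
Normalized log2 intensity of 12 genes that passed against the mouse Nanog arrays, with each array as a point and each group's mean as a bar (2 arrays per group). Kit averages 7.44 in zebrafish, 8.31 in chick and 9.86 in mouse Nanog cells, whereas Lefty2 averages 8.71, 7.79 and 6.20 in the same order.

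Changes against mouse Nanog cells ran in the same direction in zebrafish and chick Nanog cells for 68 higher and 120 lower probes, where independent lists would share 4.10 and 3.60. With 1 array left out the counts were 24 and 52 without chick replicate 1, 13 and 41 without chick replicate 2, 12 and 35 without mouse replicate 4, and 20 and 45 without mouse replicate 5. Without zebrafish replicates 1 and 2 they were 49 and 94, and 46 and 95. Lefty2 and the gap junction gene Gja1 were higher in both, and Kit, Ifitm1, Ifitm3, Tfap2c, Wfdc2, Calcoco2, Ncam1 and Meg3 lower in both. Between zebrafish and chick Nanog cells Kit differed by -0.87 (SE 0.13, adjusted p = 0.0098, but 0.102 without chick replicate 2 and 0.122 as a mean over its tested probes), whereas Tfap2c at -0.44 (SE 0.12, adjusted p = 0.121) did not pass. Across probes, which are not independent replicates, the log2 changes correlated at r = 0.568, against a mean of 0.5001 and a highest value of 0.520 in simulated unchanged groups that share the mouse arrays. Their covariance was 0.0438 against a simulated 0.0116, a difference of 0.0322. The simulated groups did not differ at all, and a difference of the mouse group alone enters both comparisons and raises both measures. The excess therefore cannot tell a change shared by zebrafish and chick Nanog cells from a difference peculiar to the mouse Nanog cultures. The correlation was 0.498 without chick replicate 1 and 0.636 without mouse replicate 5, and the simulation was not repeated for fewer arrays. The value that unchanged groups would give depends on the number of arrays per group. So these values cannot be set against 0.5001 and show neither a loss nor a gain. With only 2 mouse arrays, each comparison could not be given mouse arrays of its own with replicates. The counts of shared probes, the correlation and the covariance therefore include the effect of the shared mouse group.

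**Figure D4:**
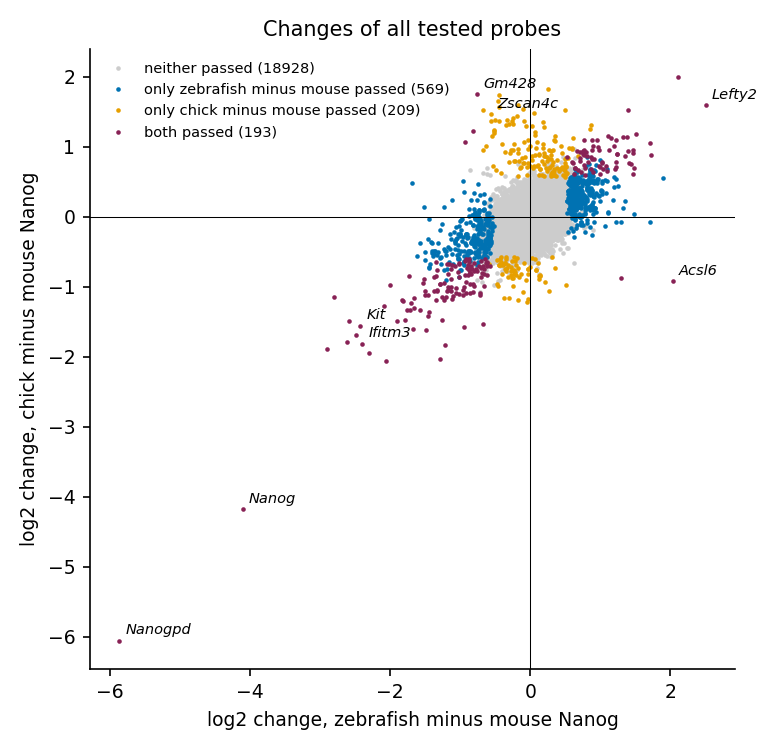
Log2 change of each tested probe in zebrafish minus mouse (horizontal axis) against chick minus mouse (vertical axis), coloured by which comparison passed. A total of 193 probes passed in both, most of them on the rising diagonal, whereas Acsl6 and Gm428 lie in opposite quadrants.

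A test across the 3 groups together found 876 probes that differed. Left out one at a time, zebrafish replicates 1 and 2 gave 496 and 525, chick replicates 1 and 2 gave 530 and 484, and mouse replicates 4 and 5 gave 358 and 428. Arrays of a group were closer to each other than to any other array, at a root mean square log2 difference of 0.235 to 0.242 within groups and 0.300 to 0.346 between them. In the exact permutation test over 15 pairings the true pairing had the smallest mean distance (one-sided p = 0.0667, the smallest this design allows). Zebrafish and mouse arrays lay farthest apart, with a mean of 0.341, against 0.310 for chick and mouse and 0.310 for zebrafish and chick.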

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

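The test on gene families was chosen only after the result was seen. The 2-cell-stage-like list moved down against mouse in zebrafish Nanog cells and up in chick Nanog cells, and its mean log2 difference between the 2 groups was -1.30 over 8 genes. With an estimated correlation of 0.285 none of the 3 list calls passed (adjusted p = 0.391 in zebrafish minus mouse, 0.229 in chick minus mouse and 0.253 in zebrafish minus chick), and with fry the fall in zebrafish minus mouse did not pass (0.0535). The version with an estimated correlation also missed a simulated shift of 0.5 in independent genes, so its result does not lay the calls on co-regulation. Array scaling or background correction as the whole cause was argued against by 4 other settings, in which the difference stayed at -0.86 or below (over 7 genes in the authors' values, 8 in the rest). It would have had to come above -0.65, a limit set from the observed -1.30. It did shrink, to -0.86 without background correction. With 1 array left out at a time it stayed at -1.26 or below, over 8 genes, or 6 where a chick array was left out (-1.54 and -1.41). One multi-copy family read by several probes was argued against too, since the 5 members past the threshold came from 4 families (Zscan4, Tcstv, Tdpoz and Gm428). A candidate explanation is a larger fraction of cells in a 2-cell-like state in the chick Nanog cultures, which was not tested, and whether such a fraction would come from the Nanog protein or from the cultures sampled stays open.

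Gm428 differed by -2.51 and Tcstv3 by -1.996 between zebrafish and chick Nanog cells, each with changes of opposite sign against mouse. BC061212, chosen after its values were seen, differed by -2.04 at 1 of its 2 tested probes, with -0.82 in zebrafish minus mouse (adjusted p = 0.0597 without mouse replicate 5) and 1.22 in chick minus mouse. Acsl6 went the other way at both probes past the threshold, by 2.95 and 2.17. These 5 probes are all that passed in opposite directions in the comparisons with mouse, and all 5 passed in zebrafish minus chick. With 1 array left out the highest adjusted p of Gm428 and Tcstv3 in zebrafish minus mouse was 0.0928 and 0.106, that of Tcstv3 in chick minus mouse 0.129, and those of the Acsl6 probes in chick minus mouse 0.157 and 0.228, so for these 3 genes passing in both directions depends on single arrays.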

How the results depend on the processing

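The list counts with median scaling were chosen after seeing the data, and every other alternative was fixed before. Counts of probes past the threshold rose with quantile normalization without background correction (1733 in zebrafish minus mouse, 980 in chick minus mouse, 996 in zebrafish minus chick, 2102 among the 3 groups), in the authors' values (1720, 958, 1020 and 2123), with offset 50 (1675, 931, 960 and 2080) and with trended and robust variance (1713, 933, 988 and 2108). At least a 2-fold change left 194, 130, 105 and 297. No filter gave 249 in chick minus mouse, the strict filter 603 in zebrafish minus chick, and the 4 arrays compared alone 264 there. With a replicate block over those 4 arrays 148 probes passed at 1 degree of freedom. The numbers share no stated origin, and replicate differences of zebrafish and chick correlated at r = -0.0142. Leaving out 1 array gave 254 to 629, 86 to 387, 61 to 293 and 358 to 530 in the same order, with the lone array assumed to vary like the others. With an estimated correlation, which also missed the simulated list shift of 0.5, 0 lists passed in each comparison, and fry gave 10 in zebrafish minus chick. With 1 array left out, 4 to 8 lists passed in zebrafish minus mouse and 3 to 9 in chick minus mouse, against 8 and 7, and 5 each time in zebrafish minus chick. The correlation of changes moved to 0.597 without background correction, 0.604 in the authors' values and 0.498 to 0.636 with 1 array left out, where the value that unchanged groups would give differs too. Beyond fewer arrays and fewer degrees of freedom, the cause was not tested. The true pairing of arrays stayed closest in all 3 other settings tried. No named gene or list past the threshold changed direction, and 84 of 156 named calls passed in every setting. Apart from Nanogpd, this tally leaves out calls named outside the rule, several of which ended in other settings, such as Tdrd1 and Slc38a4 in zebrafish minus mouse. In simulated zebrafish and mouse arrays 26.6% of changes of 0.5 were recovered, or 49.8% with 1 SD for every probe, over 19899 probes, and recovery by signal over background was not computed. A slide block was not run.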

Other observations

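The tests on the brighter mouse array, on fibroblast transcripts and on the Nanogpd probe were chosen only after the results were seen, and the genes of the next sentences were picked after their values were seen. The innate immune receptor gene Tlr2 rose by 1.32 and 1.14 on the log2 scale in zebrafish minus mouse and chick minus mouse (adjusted p = 0.00056 and 0.0021), and the gap junction gene Gja1 by 1.15 and 1.13, and both passed whichever array was left out. The germ line RNA-binding protein gene Dnd1 rose by 0.97 and 1.00 (highest adjusted p with 1 array left out 0.0579 without mouse replicate 5 and 0.0987 without chick replicate 2). Median log2 changes of chromosomes 1 to 19 and X ran from -0.05 to 0.03 over the 3 comparisons, against 0.58 for 3 copies in place of 2. Probes without a listed chromosome were left out. The Y chromosome was left out as well, so these medians do not bear on the lower Y-linked gene Eif2s3y or the sex chromosome list.

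A total of 120 probes, Kit, Ifitm3 and Tfap2c among them, were lower in both zebrafish and chick than in mouse Nanog cells. The brighter mouse array, replicate 5, as their whole cause was argued against, since 45 of them also passed as lower in both comparisons in a fit without that array, and the others stay undecided. Fibroblast-like cells in the mouse Nanog cultures stay open: over Col1a1, Col1a2, Col3a1, Fn1, Sparc and Vim the median difference, mouse minus the others, was 0.0314, but Col1a1 and Col3a1 were detected on no array and Col1a2 on 1, and Fn1 and Sparc were bright in every group. Vim was higher in mouse by 0.88, and Nnmt (-1.50 in zebrafish minus mouse, -1.11 in chick minus mouse), Igfbp7 (-1.46 and -1.11), S100a6 (-1.14 and -1.01) and Pcolce (-0.91 and -0.93), picked after their values were seen, are among the 120 (with 1 array left out the chick minus mouse calls ended at an adjusted p of up to 0.0561 for Nnmt, 0.0626 for S100a6 and 0.252 for Pcolce without mouse replicate 4, and 0.126 for Igfbp7 without mouse replicate 5, and in zebrafish minus mouse that of Pcolce at 0.197 without mouse replicate 4). The fixed fibroblast and mesenchymal list did not shift with camera (adjusted p = 0.719 in zebrafish minus mouse and 0.978 in chick minus mouse). Its member Snai1 went the other way, higher by 0.75 and 0.94, and 11 of its 25 members were measured. The Nanog protein used and differences between clones or cultures stay open as well, since the design does not separate them.

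The Nanogpd probe was bright on the mouse arrays alone. A mouse Nanog transcript reaching the pseudogene probe is a candidate explanation that the values leave open. Both this probe and the Nanog probe ILMN_1245732 were above 8 on the log2 scale on the same 2 arrays, but between mouse replicates 5 and 4 they differed in opposite directions (by 0.07 and -0.05), each by less than the median residual SD of 0.14. A mislabelled or swapped single array was argued against, since over all tested probes each of the 6 arrays lay nearest to the other array of its label, whereas an exchange of both arrays between groups was not tested. Transcription of the pseudogene itself was not tested and stays open.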
